A study of Rattus norvegicus with 30 samples.

How the data were processed

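Total RNA of rat testes, taken by Trizol extraction and RNeasy columns per the labels, was hybridised to 1-colour Affymetrix Rat230_2 arrays with biotin labelling, 1 array per animal. There were 15 MEHP and 15 corn oil animals, 3 at each of 1, 2, 3, 6 and 12 h. Groups and animal numbers were taken from the labels. The deposited values are an intensity per probe set, linear and scaled by the authors, and GCOS 1.0 is named per the submitters' processing notes. The summary method and the scaling target are not given in the sources used here. The values were checked: the 2% trimmed mean was 500.1 to 500.2 on every array, no 2 arrays held identical values, the median signal ran from 117.2 to 165.4 and the sum of signals from 20531801 to 21687686. Scanning dates and raw image files were not analysed here.

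Of 31099 probe sets, 57 control probe sets were left out of the tests and used as measures of array processing, 18 of them bacterial spike controls. Of the other 31042, 20826 had 1 gene symbol, 436 several and 9780 no listed gene. Probe sets with several symbols or none were tested and counted but not named. Of those with 1 symbol 20758 were matched to a current gene table by Entrez number, which changed 0 symbols. Signals were used as log2(signal + 16), which shrinks the folds of low signals. Probe sets at or above the 40th percentile of an array (66.7 to 93.6) in at least 3 arrays were tested, 21190 in all, of which 15733 had 1 symbol and stood for 11280 genes.

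One linear model with a mean for each of the 10 groups was fitted in limma 3.58.1 (R 4.3.3) with 20 residual degrees of freedom, moderated with a trend to 24.2 in total. The contrasts were MEHP minus corn oil at each time, the 5 contrasts together (any time), their 4 differences (time dependence), their mean, and the differences between times among corn oil animals. P values were adjusted by Benjamini-Hochberg over all probe sets tested, per contrast, with a threshold of 0.05. The residual SD of an array in log2 ran from 0.166 to 0.421. No paired analysis was possible because the animal numbers are unique and no 2 groups share them.

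Gene lists, 26 with 516 genes of which 383 were measured, were fixed together with the models, contrasts, thresholds and named genes rule before the data were examined. A gene was represented by its probe set of highest mean signal. The lists were immediate early genes, cholesterol synthesis and uptake, steroidogenesis, PPAR targets and fatty acid oxidation, cytokines with chemokines and adhesion, apoptosis and p53, glucocorticoid responsive genes, and circadian clock. Further lists were oxidative stress (NRF2), endoplasmic reticulum and amino acid stress, heat shock, cell junction and Sertoli cytoskeleton, matrix remodelling, and TGF-beta with activin and inhibin. Marker lists covered Sertoli, Leydig, peritubular myoid and endothelial cells, spermatogonia, spermatocytes, spermatids, macrophages, neutrophils, lymphocytes, erythrocytes, and the epididymis and rete. Some genes stand in more than 1 list. Lists with at least 5 measured members, 24 of the 26, were tested with camera at a preset correlation of 0.01, adjusted over lists and times together. A list score, the mean log2 over members, was compared over all times by 100000 permutations within times (2-sided) and for time dependence by an F test on the 30 scores, each adjusted over lists.

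Named genes were, per time, up to 12 with the largest increase and 12 with the largest decrease among genes past the threshold with 1 symbol whose 3 MEHP animals lay on 1 side of the 3 corn oil animals. Where fewer than 5 passed, the 5 of smallest p were added. Fixed sentinel genes at all times and the members of lists that passed were named as well. The sentinel genes Btg2, Hmgcs1 and Pdk4 had no probe set tested with 1 symbol.

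The model was tested on simulated data with 50 probe sets changed per fold and time. With independent noise it recovered 28 to 36% of 1.5-fold changes, 56 to 64% of 2-fold, 90 to 98% of 4-fold and 96 to 100% of 8-fold, with 2, 3, 4, 5 and 11 false calls at 1, 2, 3, 6 and 12 h. With the residuals of the real arrays shuffled between arrays it recovered 20 to 34%, 56 to 62%, 90 to 98% and 98 to 100%, with 64 false calls at 2 h and 0 at each other time. For 1.5-fold, 2-fold, 4-fold and 8-fold changes in turn, independent noise gave 36, 62, 96 and 96% at 1 h, 30, 60, 98 and 100% at 2 h, 28, 64, 94 and 98% at 3 h, 32, 56, 90 and 100% at 6 h, and 30, 58, 94 and 96% at 12 h. Shuffled residuals gave 22, 56, 98 and 98% at 1 h, 34, 56, 96 and 100% at 2 h, 20, 62, 94 and 98% at 3 h, 22, 60, 94 and 98% at 6 h, and 24, 62, 90 and 98% at 12 h. The list test called a simulated list of 20 genes raised by 0.5 in log2 at 12 h. Of 200 random lists 7 reached the 0.05 level without adjustment. Genes drawn at random need not share the correlation of the real lists, estimated at up to 0.471 (spermatid markers). The random lists therefore did not test the preset correlation.

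Alternatives were quantile normalization, median centring, log2(signal + 1) and log2(signal + 64), no filter, the 60th percentile as filter, robust moderation and no trend. Others were the RNA integrity number (29 of 30 animals have one) and the gavage volume (0.178 to 0.305 ml) as covariates. The fit with the first left out corn oil 6 h animal 35, which has no such number. Also run were the 6 arrays of a time alone, a 1.5-fold minimum, and adjustment over the 5 times together. Further ones were an estimated correlation in camera, the mean of all probe sets of a gene for lists, each other probe set of a gene, and each of the 30 animals left out in turn. Corn oil 2 h animal 7, whose number lies outside the run of the others, was among the latter. Array weights, covariates for the array's median signal, its spermatid marker score and its spike level, omission of 8 arrays whose median signal lay over 10% from the median of all, omission of the 6 arrays of 2 h, and the 2 h MEHP animals against 1 h corn oil animals were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.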

Results

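Testes of male Fischer rats of postnatal day 28 were examined 1, 2, 3, 6 or 12 h after a gavage of mono-(2-ethylhexyl) phthalate (MEHP) at 1 g/kg, or of corn oil alone. MEHP is the active metabolite of the plasticizer di-(2-ethylhexyl) phthalate, and the Sertoli cell, which nurses the germ cells, is its best known target in the testis. Each of the 10 groups held 3 animals, and each animal had its own array. The 2% trimmed mean of the signals was 500.1 to 500.2 on all 30 arrays, which scaling to a common mean would give by itself. It does not show that the arrays were alike otherwise, as their median signals ran from 117.2 to 165.4. The log2 signals of 2 animals of a group correlated with r between 0.911 and 0.987 (median 0.978 over 30 pairs). Animals of the 2 h groups had the lowest mean RNA integrity numbers, 8.27 ± 0.06 (SD, n = 3) after corn oil and 8.43 ± 0.06 after MEHP. Below, a change is MEHP minus corn oil at the same time in log2(signal + 16) with its standard error and n = 3 animals per group, and p is adjusted over 21190 probe sets.

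Cxcl1, a chemokine that attracts neutrophils, was higher after MEHP at 4 of the 5 times, by 10.2-fold at 2 h, 12.0-fold at 3 h, 32.5-fold at 6 h and 79.3-fold at 12 h. Its corn oil signals, with means of 3.66 to 33.2 at these times, lay below the 40th percentile of the arrays (66.7 to 93.6). The size of its folds therefore depends on the added 16, and no order of times is read from them. The same holds for the folds of other genes with corn oil signals below that level, which include Fos, Atf3, Nfkb2, Ccl2, Ccl7, Ccl20, Fst, Gbp4, Calcb, Reg3b, Plaur and Fas at 12 h. Cyp17a1, the enzyme of Leydig cells that makes androgen precursors, fell to 0.0964 of its corn oil level at 12 h, by means of log2 values. The fall of its mean signal was smaller. Over all genes, limma called 0 probe sets at 1 h, 140 at 2 h (47 higher, 93 lower), 9 at 3 h (all higher), 43 at 6 h (38 higher, 5 lower) and 1852 at 12 h (1072 higher, 780 lower). At least 2-fold changes made up 24 of these at 2 h, 8 at 3 h, 34 at 6 h and 763 at 12 h.

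**Figure D1:**
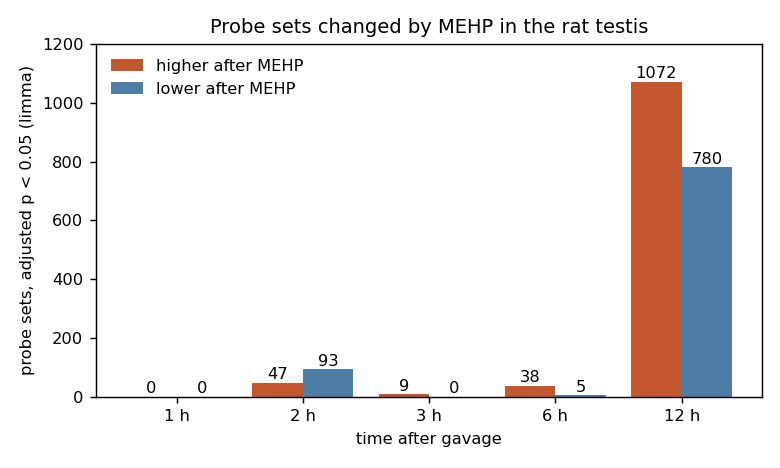
Probe sets higher and lower after MEHP at each time (limma, adjusted p under 0.05, 3 animals per group). Times are equally spaced on the axis.

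At 1 h no gene passed the test. Egr1, an immediate early transcription factor, had a mean signal of 847.7 ± 152.8 (SD, n = 3) after MEHP and 293.6 ± 48.6 after corn oil, a log2 difference of 1.48 ± 0.44 with an adjusted p of 0.941. Fos, another immediate early factor, had 118.5 ± 13.9 and 38.5 ± 18.4 (1.36 ± 0.59, adjusted p = 0.941). The other genes of smallest p were Rab11fip2 (1.62 ± 0.40), the exchange factor Spata13 (-0.61 ± 0.16), the adaptor Crkl (0.56 ± 0.16) and the proteoglycan Acan (1.28 ± 0.38), none of which passed. limma called 0 probe sets, and 518 had an unadjusted p under 0.05, against 1060 expected by chance. Without corn oil 1 h animal 40 the count was 1.

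Of the 24 gene lists tested, 3 differed at 1 h as groups, with 0 members past the threshold in each, over all genes or adjusted over the list alone. Genes of cell junctions and the Sertoli cytoskeleton had a median of -0.13, with 24 of 26 members lower (adjusted p = 0.00362, and adjusted p = 0.547 with an estimated correlation). The TGF-beta, activin and inhibin list had a median of -0.16, with 17 of 21 lower (adjusted p = 0.0368, and adjusted p = 0.404 with an estimated correlation). The call of the TGF-beta list was lost without corn oil animals 40 (adjusted p = 0.078) and 41 (adjusted p = 0.0558) and MEHP animals 37 (adjusted p = 0.0778) and 38 (adjusted p = 0.0776). Spermatid markers had a median of 0.31, with 13 of 14 higher (adjusted p = 0.00362, and adjusted p = 0.507 with an estimated correlation). With gavage volume as a covariate the mean of the junction list was 0.03 and that of the spermatid list was -0.07, both with the opposite sign, and that of the TGF-beta list was -0.0342 beside -0.162 (adjusted p = 0.733). With the spermatid score as a covariate the junction and TGF-beta calls were lost (means -0.00837 and -0.0689, adjusted p = 0.969 and 0.383). With the array median as a covariate all 3 were lost (-0.0316, -0.0742 and 0.11, adjusted p = 0.542, 0.179 and 0.494).

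At 2 h immediate early genes and 1 chemokine were among the genes that rose. Cxcl1 rose 10.2-fold (log2 3.36 ± 0.41, adjusted p = 0.00023), from a mean signal of 33.2 ± 29.2 to 422.1 ± 91.1. Egr1 rose 8.31-fold (3.06 ± 0.44, adjusted p = 0.00167) and Ccn1, a matricellular protein that binds integrins, 3.95-fold (1.98 ± 0.23, adjusted p = 0.000141). Ier3, a stress-inducible regulator of cell survival, rose 2.74-fold (1.45 ± 0.23, adjusted p = 0.00509). Fos also rose, by 6.52-fold (2.70 ± 0.59, adjusted p = 0.0354). The call of Fos was lost without corn oil animals 47 (adjusted p = 0.0844) or 48 (adjusted p = 0.0647) and without MEHP animals 43 (adjusted p = 0.146), 44 (adjusted p = 0.121) or 45 (adjusted p = 0.101).

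Of 34 immediate early genes measured, 6 rose at 2 h (16 adjusted over the list alone) and 28 did not pass. Their median was 0.52 (adjusted p = 5.28e-12, and adjusted p = 0.124 with an estimated correlation). The phosphatases Dusp5 (1.46 ± 0.35) and Dusp1 (1.13 ± 0.26), which switch off MAP kinases, were the other members that rose. The other probe set of Dusp1 gave 0.06 (adjusted p = 0.97). Single omissions ended the call of Dusp5 for 22 of the 30 animals (adjusted p from 0.0504 to 0.158), all but 57, 58, 37, 49, 50, 51, 31 and 33. They ended that of Dusp1 for 15 (adjusted p from 0.0505 to 0.155), animals 60, 40, 42, 48, 7, 52, 34, 35, 36, 43, 44, 45, 51, 31 and 32. Of 25 cytokine, chemokine and adhesion genes, Cxcl1 rose (3 rose adjusted over the list alone). The median of that list was 0.15 (adjusted p = 0.0412, and adjusted p = 0.435 with an estimated correlation). The cytokine call was lost without corn oil 2 h animal 47 (mean 0.185 beside 0.292, adjusted p = 0.165), MEHP 2 h animal 44 (adjusted p = 0.0742) or MEHP 3 h animal 49 (adjusted p = 0.0551).

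The genes that fell at 2 h included the DNA repair factor Nsmce4a (-0.90 ± 0.14, adjusted p = 0.00509), and Txnip, an inhibitor of thioredoxin and of glucose uptake (-1.03 ± 0.21, adjusted p = 0.0272). Zfp703, a transcriptional corepressor, fell by 1.71 ± 0.33 (adjusted p = 0.0202), a call lost without corn oil animal 48 (adjusted p = 0.133) or MEHP animal 44 (adjusted p = 0.139). The call of Txnip was lost without corn oil animal 48 (adjusted p = 0.135) or MEHP animals 43 (adjusted p = 0.113), 44 (adjusted p = 0.0752) or 45 (adjusted p = 0.101). Macrophage and monocyte markers were lower in 18 of 19 members, with a median of -0.47, although only the complement gene C1qb (-0.88 ± 0.20) fell past the threshold (5 fell adjusted over the list alone). The test of the macrophage list gave an adjusted p = 1.66e-06, and adjusted p = 0.183 with an estimated correlation. The C1qb call was lost without any of 15 animals, 60, 62, 42, 48, 7, 52, 34, 36, 38, 43, 44, 45, 51, 31 and 32 (adjusted p from 0.0504 to 0.198). All 16 Sertoli cell markers were lower, with a median of -0.30 and 0 past the threshold by limma (4 adjusted over the list alone). Their test gave an adjusted p = 0.000168, and adjusted p = 0.404 with an estimated correlation. Without corn oil animal 48 their mean of -0.285 became -0.14 (adjusted p = 0.035).

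Dmrt1, a transcription factor of Sertoli cells and spermatogonia, fell by 0.64 ± 0.12 at 2 h (adjusted p = 0.0157), alone among 7 spermatogonia markers (2 adjusted over the list alone). The Dmrt1 call was lost without corn oil animal 48 (adjusted p = 0.104) or MEHP animals 44 (adjusted p = 0.12) or 45 (adjusted p = 0.0554). The spermatogonia list had a median of -0.19 (adjusted p = 0.0381, and adjusted p = 0.404 with an estimated correlation). This list call was lost without corn oil animals 47 (adjusted p = 0.13) or 48 (mean -0.108 beside -0.216, adjusted p = 0.114), whereas without corn oil animal 7 the mean was -0.376. With gavage volume as a covariate the mean was -0.124 (adjusted p = 0.125). It was also lost without MEHP 2 h animals 44 (adjusted p = 0.0539) or 45 (adjusted p = 0.0829), MEHP 3 h animal 49 (adjusted p = 0.0533) or MEHP 12 h animal 57 (adjusted p = 0.0527). Of 17 oxidative stress genes of the NRF2 pathway, Gstm1, a glutathione transferase, fell (-0.50 ± 0.12), with 2 higher and 5 lower adjusted over the list alone. The NRF2 list had a median of -0.19 (adjusted p = 0.0491, and adjusted p = 0.404 with an estimated correlation). Its call was lost without any of 18 animals, 60, 62, 40, 41, 7, 52, 53, 54, 34, 35, 36, 37, 38, 43, 45, 50, 32 and 33 (adjusted p from 0.05 to 0.315), and its mean of -0.0846 was -0.0261 without animal 7. That of Gstm1 was lost without any of 16, 60, 61, 62, 40, 41, 42, 48, 52, 34, 36, 38, 43, 44, 45, 31 and 32 (adjusted p from 0.0504 to 0.213).

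The corn oil and MEHP arrays of 2 h differed in measures of array processing. The mean log2 signal of 18 bacterial spike probe sets was 11.8 ± 0.485 (SD, n = 3) on the 2 h corn oil arrays and 11.1 ± 0.164 on the 2 h MEHP arrays. Corn oil and MEHP means at the other times were 11.04 and 10.93 (1 h), 11.72 and 11.68 (3 h), 11.09 and 10.98 (6 h), and 11.69 and 11.74 (12 h). The 2 h corn oil mean was thus near those of 3 h and 12 h and the 2 h MEHP mean near those of 1 h and 6 h. Corn oil animal 7, at 11.24, was near MEHP animal 43, at 11.23. The log2 ratio of 3' to 5' hexokinase signals, a sign of RNA or labelling quality, was 0.494 ± 0.0433 after corn oil and 0.764 ± 0.0155 after MEHP at 2 h. Corn oil and MEHP means of this ratio were 0.718 and 0.961 at 1 h, and 0.714 and 0.495 at 3 h. They were 0.825 and 0.849 at 6 h, and 0.695 and 0.578 at 12 h. Gaps of similar size thus stood at 1 h and 3 h, with larger SDs (0.106 to 0.41) than at 2 h. Of 57 control probe sets, 19 differed between the groups at 2 h (smallest adjusted p = 2.32e-05) and 0 at each other time by limma.

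**Figure D2:**
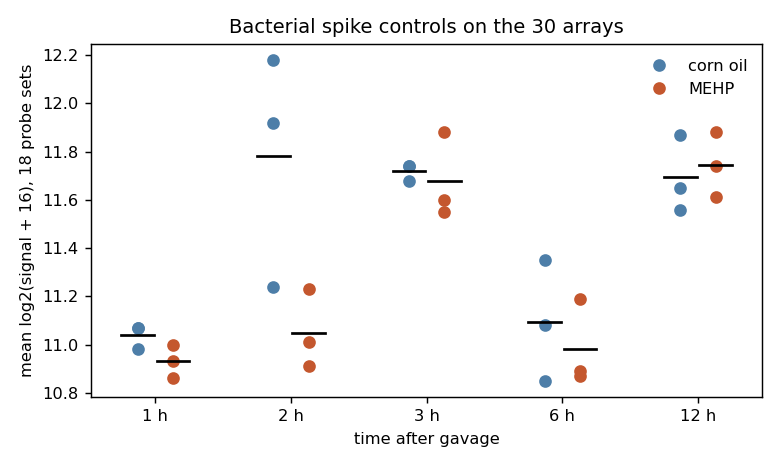
Mean log2 signal of 18 bacterial spike probe sets on each array. Each point is 1 animal. Times are equally spaced on the axis.

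Egr1, Cxcl1, Ccn1 and Ier3 were also called when the 2 h MEHP animals were set against the 1 h corn oil animals, a comparison chosen after the data were seen. The changes were then 2.87, 4.36, 2.09 and 1.63 (adjusted p = 0.0045, 3.16e-06, 2.52e-05 and 0.00169). These 4 were the only calls of that comparison, all higher, so that none of the 93 decreases was called. Against the 1 h corn oil animals their median was -0.113 beside -0.609, and that of the 47 increases was 0.124 beside 0.695. Tuba8, Lurap1l, Cfc1, Macroh2a2 and Zfp617 also rose at 2 h (1.652, 1.308, 1.224, 0.951 and 0.881). Against the 1 h corn oil animals they had 0.065, 0.988, 0.188, 0.274 and 0.162. With the spike level as a covariate the count at 2 h was 13, all higher. All 93 decreases kept their direction, with a median change of -0.49 (median standard error 0.18) beside -0.609 (0.132) without it. Standard errors grew in part because the spike level differed between these groups. Txnip had -0.88 ± 0.29, Zfp703 -1.43 ± 0.46 and C1qb -0.97 ± 0.29, close to their values without it, whereas Nsmce4a had -0.62 ± 0.18 and the hexokinase Hk2 -0.47 ± 0.25 beside -0.90 for both. The Hk2 call was also lost without animals 47, 48, 43, 44 or 45 (adjusted p from 0.0579 to 0.204). The calls lost with this covariate therefore do not settle whether processing caused these decreases. Cxcl1 and Ier3 were not among the 13 (2.60 ± 0.53 and 1.39 ± 0.32, adjusted p = 0.0539 and 0.0782). The cytokine, NRF2, Sertoli and spermatogonia list calls were lost too. Their means were 0.107 (beside 0.292), -0.136 (-0.0846), -0.183 (-0.285) and 0.0615 (-0.216), with adjusted p = 0.248, 0.0524, 0.0951 and 0.889. In simulated data with residuals shuffled between the arrays of all times, 64 false calls fell at 2 h and 0 at each other time. The residuals placed at 2 h came from any array in a single shuffle, so these 64 say nothing about the 2 h arrays in particular. They show that residuals of real arrays can bring 64 false calls to a contrast at this threshold, in data that also held changed probe sets. This was more than the 9 called at 3 h and the 43 at 6 h. Without 1 animal the count of 140 became 11 (MEHP 44), 12 (MEHP 45), 22 (corn oil 48), or 29 (MEHP 43). It became 90 (corn oil 3 h animal 52), 90 (corn oil 6 h animal 34), 91 (MEHP 1 h animal 38), or 92 (corn oil 6 h animal 36), and rose to 308 (MEHP 3 h animal 49), 318 (MEHP 12 h animal 57) or 330 (corn oil 2 h animal 7).

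At 3 h 9 genes rose and 0 fell by limma. Cxcl1 rose 12.0-fold (3.58 ± 0.41, adjusted p = 7.11e-05), Ccn1 4.14-fold (2.05 ± 0.23, adjusted p = 7.11e-05), and its relative Ccn2, a growth factor of connective tissue, 4.01-fold (2.01 ± 0.24, adjusted p = 9.46e-05). Cebpd, a transcription factor of the acute phase response, rose 3.63-fold (1.86 ± 0.26, adjusted p = 0.00121), and its other probe set gave 1.67 without passing (adjusted p = 0.312). The rest were Dusp1 (1.64 ± 0.26), Ier3 (1.5 ± 0.23), Egr1 (2.47 ± 0.44), Tnfaip3, an inhibitor of NF-kB signalling (1.22 ± 0.22), and Errfi1, an inhibitor of the EGF receptor (0.92 ± 0.17). The other probe set of Dusp1 gave 1.02 (adjusted p = 0.478). At an unadjusted p under 0.05 there were 2140 probe sets.

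Calls of 5 of these genes were lost without single animals of 3 h. These were Dusp1 without corn oil animal 52 (adjusted p = 0.0801) or MEHP animal 49 (adjusted p = 0.0879), and Ier3 without MEHP animal 49 (adjusted p = 0.0642). Egr1 was lost without corn oil animals 52 (adjusted p = 0.212) or 54 (adjusted p = 0.0502) or MEHP animals 49 (adjusted p = 0.326) or 50 (adjusted p = 0.143). Tnfaip3 was lost without corn oil animal 53 (adjusted p = 0.233) or MEHP animals 50 (adjusted p = 0.148) or 51 (adjusted p = 0.174). Errfi1 was lost without corn oil animals 52 (adjusted p = 0.141) or 53 (adjusted p = 0.212) or MEHP animals 49 (adjusted p = 0.351) or 51 (adjusted p = 0.0773). The count was 37 without corn oil animal 54 and 5 without MEHP animal 49.

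Among lists at 3 h, immediate early genes had 6 of 34 members that rose (16 adjusted over the list alone) and a median of 0.64 (adjusted p = 6.24e-24, and adjusted p = 0.0136 with an estimated correlation). Cytokines, chemokines and adhesion genes had 3 of 25 (8 adjusted over the list alone) and a median of 0.53 (adjusted p = 8.29e-12, and adjusted p = 0.00339 with an estimated correlation). Glucocorticoid responsive genes had 2 of 13 (3), Dusp1 and Errfi1, which belong to the immediate early list as well, and a median of 0.15 (adjusted p = 0.000783, and adjusted p = 0.154 with an estimated correlation). The glucocorticoid call was lost with the array median as a covariate (mean 0.186 beside 0.285, adjusted p = 0.0843). Cell junction genes were higher in 22 of 26 members, with 0 past the threshold either way and a median of 0.24 (adjusted p = 1.33e-05, and adjusted p = 0.404 with an estimated correlation). That call was lost without MEHP animal 49 (mean 0.0826 beside 0.261, adjusted p = 0.112) and with the array median as a covariate (0.0889, adjusted p = 0.113). Matrix remodelling genes were higher in 19 of 22, with 0 past the threshold (1 adjusted over the list alone) and a median of 0.19 (adjusted p = 0.000387, and adjusted p = 0.339 with an estimated correlation). Without animal 49 their mean of 0.25 became 0.15 (adjusted p = 0.00942).

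Leydig cell lists were higher as groups at 3 h without a member past the threshold (0 by limma). The Leydig marker score was 8.861 to 8.941 in the 3 h corn oil animals, below every other corn oil animal, and 9.013 to 9.528 after MEHP. Steroidogenesis genes had a median of 0.17, with 10 of 15 members higher (adjusted p = 0.0294, and adjusted p = 0.404 with an estimated correlation). Leydig cell markers had a median of 0.17, with 8 of 11 higher and 2 that rose adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.352 with an estimated correlation). The steroidogenesis call was lost without corn oil animals 53 (adjusted p = 0.0536) or 54 (adjusted p = 0.0634), MEHP 3 h animals 50 (adjusted p = 0.201) or 51 (adjusted p = 0.164) or MEHP 12 h animal 57 (adjusted p = 0.0522). Without MEHP animal 49 its mean of 0.285 became 0.431. That of the Leydig markers was lost without MEHP 3 h animals 50 (adjusted p = 0.143) or 51 (adjusted p = 0.141).

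At 6 h chemokine and immediate early genes were again higher after MEHP. Cxcl1 rose 32.5-fold (5.02 ± 0.41, adjusted p = 1.75e-07), from a signal of 3.66 ± 1.51 to 632.1 ± 137.3, and Ccn1 and Ccn2 rose 6.19-fold and 5.48-fold (2.63 ± 0.23 and 2.46 ± 0.24, adjusted p = 2.7e-07 and 2.01e-06). Dusp1, Dusp5, Ier3 and Egr1 rose 5.16-fold, 5.64-fold, 4.31-fold and 7.05-fold, and the other probe set of Dusp1 gave 1.77 (adjusted p = 0.0714). Members of the family of NF-kB inhibitors rose too, Nfkbiz 4.77-fold (2.26 ± 0.30, adjusted p = 0.00026) and Nfkbia 1.77-fold (0.82 ± 0.12, adjusted p = 0.00078), as did Ppp1r15a, a phosphatase subunit of the integrated stress response, by 2.27-fold (1.19 ± 0.19, adjusted p = 0.00244). Of the immediate early genes 12 of 34 rose (18 adjusted over the list alone), with a median of 0.79 (adjusted p = 2.85e-35, and adjusted p = 0.00324 with an estimated correlation). Of the cytokine list 5 of 25 rose (9), with a median of 0.59 (adjusted p = 8.57e-17, and adjusted p = 0.000746 with an estimated correlation).

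Other genes that rose at 6 h depended on single animals. Fos rose 7.87-fold (2.98 ± 0.59, adjusted p = 0.0252), a call lost without corn oil animals 34 (adjusted p = 0.101), 35 (adjusted p = 0.147) or 36 (adjusted p = 0.122) and MEHP animals 32 (adjusted p = 0.205) or 33 (adjusted p = 0.165). Atf3, a stress transcription factor, rose by 2.44 ± 0.40 (lost without corn oil animal 36, adjusted p = 0.071, or MEHP animal 32, adjusted p = 0.0611). Edn1, the vasoconstrictor endothelin, rose by 1.91 ± 0.32 (lost without corn oil animal 35, adjusted p = 0.0747, or MEHP animal 32, adjusted p = 0.0611). The cytokine Il1a (1.28 ± 0.27), the NF-kB subunit Nfkb2 (1.87 ± 0.39) and the chemokine Cxcl10 (1.27 ± 0.27) had adjusted p values of 0.0408, 0.0408 and 0.0451, and none was stable. The other probe set of Il1a gave 1.21 (adjusted p = 0.175). Omission of animals 60, 40, 41, 42, 47, 52, 53, 34, 35, 36, 38, 43, 44, 32 or 33 ended the call of Il1a (adjusted p from 0.0514 to 0.257). Omission of animals 62, 40, 41, 42, 47, 52, 53, 34, 36, 38, 43, 44, 45, 32 or 33 ended that of Nfkb2 (adjusted p from 0.0513 to 0.323). For Cxcl10 these were animals 60, 61, 62, 41, 47, 7, 52, 53, 54, 34, 35, 36, 38, 43, 44, 45, 50, 32 and 33 (adjusted p from 0.0509 to 0.487). The count of 43 at 6 h became 22, 18, 17 and 13 without corn oil animals 34, 35 and 36 and MEHP animal 32, 68 without MEHP 12 h animal 57 and 75 without MEHP 3 h animal 49.

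Leydig cell genes were lower at 6 h. Star, which delivers cholesterol to the mitochondrion in steroidogenic cells, fell to 0.283 of its corn oil level (-1.82 ± 0.38, adjusted p = 0.0408), from a signal of 681.8 ± 222.1 to 174.9 ± 16.8. Its other probe set gave -1.62 (adjusted p = 0.0714). Steroidogenesis genes were lower in 13 of 15 members, 1 of which fell past the threshold (3 adjusted over the list alone), with a median of -0.55 (adjusted p = 1.12e-06, and adjusted p = 0.0346 with an estimated correlation). All 11 Leydig cell markers were lower, 1 past the threshold (1), with a median of -0.55 (adjusted p = 1.29e-05, and adjusted p = 0.0346 with an estimated correlation). The Leydig marker score was 9.555 to 9.648 in the 6 h corn oil animals and 8.871 to 9.051 after MEHP. In the 3 h corn oil animals it was 8.861 to 8.941, close to the 6 h MEHP values, so controls of different times differed too. The acetyltransferase Nat8f5 also fell (-1.44 ± 0.27, adjusted p = 0.0139), as did the receptor Mrgprf (-1.38 ± 0.29, adjusted p = 0.0451). The Star call was lost in 13 of the 30 omissions (adjusted p from 0.0512 to 0.324), which included all 6 animals of 6 h, corn oil animals 60, 40 and 47 and MEHP animals 59, 37, 38 and 43. The Nat8f5 call was lost without animals 34 (adjusted p = 0.101), 35 (adjusted p = 0.101), 31 (adjusted p = 0.1) or 32 (adjusted p = 0.164) of 6 h. The Mrgprf call was lost without any of 21 animals, all but 48, 7, 52, 54, 57, 58, 49, 51 and 31 (adjusted p from 0.0552 to 0.229). With the RNA integrity number as a covariate 20 probe sets were called at 6 h, all higher, and Star was not among them. The change of Star was then -1.61 ± 0.44, not far from that without the covariate (adjusted p = 0.328, range 0.0124 to 0.696 over its alternatives). That fit also left out corn oil animal 35, which has no such number. Without this animal alone 18 of the 43 calls at 6 h stood, beside 19 with the covariate. The loss of calls can therefore not be credited to RNA integrity.

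Smaller group shifts stood beside these at 6 h. Glucocorticoid responsive genes had a median of 0.24, and Dusp1 and Errfi1 were the 2 of 13 members that rose (3 adjusted over the list alone, adjusted p = 1.63e-05, and adjusted p = 0.0648 with an estimated correlation). The Errfi1 call was lost without corn oil animals 34 (adjusted p = 0.0556), 35 (adjusted p = 0.101) or 36 (adjusted p = 0.071) or MEHP animals 32 (adjusted p = 0.0815) or 33 (adjusted p = 0.114). It was also lost with the RNA integrity number as a covariate (adjusted p = 0.0821), in a fit that left out animal 35 as well. Junction genes had a median of 0.20, with 22 of 26 higher and 0 past the threshold (4 adjusted over the list alone, adjusted p = 2.93e-06, and adjusted p = 0.392 with an estimated correlation). Sertoli cell markers (median 0.19, 13 of 16 higher) and peritubular myoid markers (median 0.17, 10 of 12 higher) had 0 members past the threshold, and 0 and 1 adjusted over the list alone. Their adjusted p values were 0.00341 and 0.0174, and adjusted p = 0.5 for both with an estimated correlation. Spermatid markers were lower in 12 of 14 (median -0.42, adjusted p = 0.00341, and adjusted p = 0.501 with an estimated correlation). Endothelial markers were lower in 7 of 11 (median -0.09, adjusted p = 0.0491, and adjusted p = 0.154 with an estimated correlation). Neither list had a member past the threshold, over all genes or adjusted over the list alone (0 by limma). Without corn oil animal 36 the Sertoli and spermatid calls were lost (means 0.0925 and -0.277 beside 0.161 and -0.446, adjusted p = 0.0534 and 0.121). Without MEHP animal 33 these means were 0.247 and -0.687, and without MEHP animal 32 the Sertoli mean was 0.1 (adjusted p = 0.046). With the spermatid score as a covariate the Sertoli call was lost (mean 0.0551, adjusted p = 0.336). With gavage volume the spermatid mean was -0.203 (adjusted p = 0.126). The myoid call was lost without animals 34 (adjusted p = 0.154) or 33 (adjusted p = 0.191). The endothelial call was lost without animals 61, 40, 41, 47, 48, 7, 34, 35, 37, 43, 44, 49, 50, 32 or 33 (adjusted p from 0.0501 to 0.19).

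At 12 h chemokines were among the genes that rose. Cxcl1 rose 79.3-fold (6.31 ± 0.41, adjusted p = 6.99e-10), and Ccl2, Ccl20 and Ccl7, which attract monocytes and lymphocytes, rose 38.2-fold, 32.9-fold and 13-fold (5.26 ± 0.57, 5.04 ± 0.57 and 3.70 ± 0.50, adjusted p = 8.67e-07, 1.91e-06 and 1.51e-05). Nfkb2, an NF-kB subunit, rose 16.7-fold (4.06 ± 0.39), and Icam1, a leukocyte adhesion receptor, 9.80-fold (3.29 ± 0.40). Of the 25 genes of the cytokine list 20 rose and 0 fell by limma (21 and 0 adjusted over the list alone), with a median of 2.10 (adjusted p = 2.78e-31, and adjusted p = 1.56e-05 with an estimated correlation). Immediate early genes had 23 of 34 that rose (27 adjusted over the list alone) and a median of 1.64 (adjusted p = 2.07e-29, and adjusted p = 0.00568 with an estimated correlation). Fos was 21.6-fold higher (4.43 ± 0.59), Ccn1 11.1-fold (3.48 ± 0.23), Egr1 10.4-fold (3.38 ± 0.44) and Atf3 10.1-fold (3.34 ± 0.40). The orphan receptor Nr4a1 rose by 2.18 ± 0.41 (adjusted p = 0.000711) and Cebpd by 2.87 ± 0.26 (adjusted p = 1.12e-07).

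**Figure D3:**
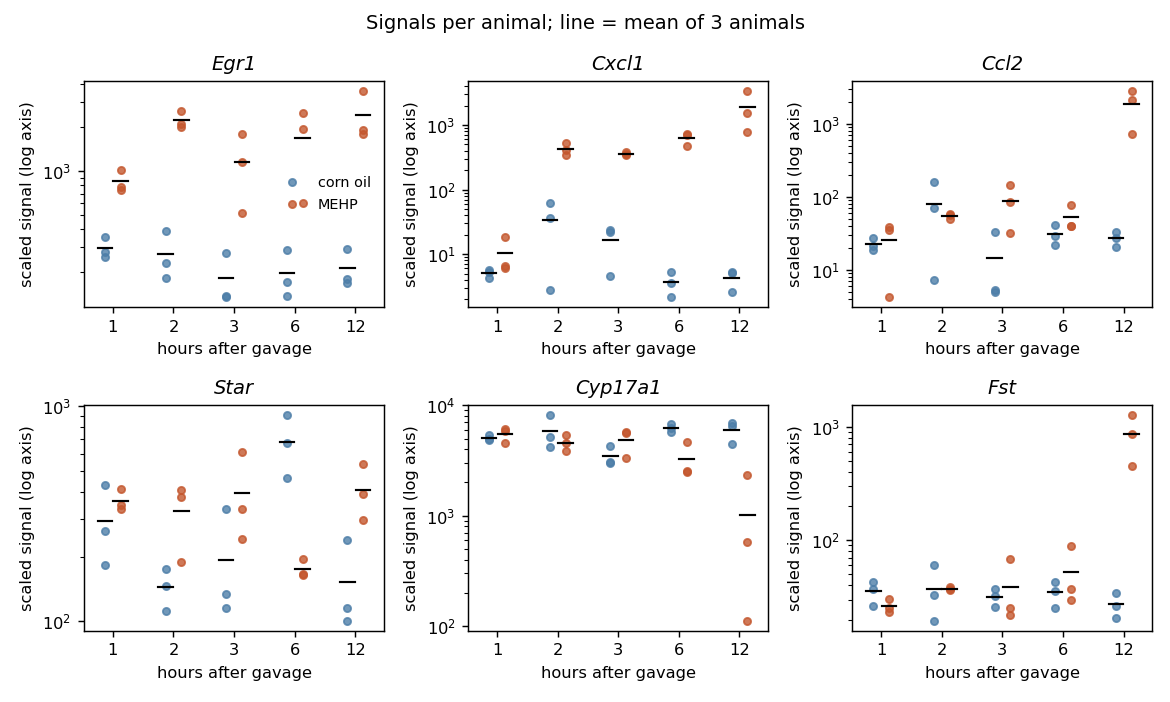
Signals of selected genes in each animal on a log axis, with lines through the means of 3 animals per group. Times are equally spaced on the axis.

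Of the genes with large increases at 12 h, several stand outside these lists. The activin antagonist Fst rose 18.9-fold (4.24 ± 0.35, adjusted p = 3.29e-08), from 27.2 ± 7.05 to 860.8 ± 409.1 (a fold that depends on the added 16), the guanylate binding protein Gbp4 19.6-fold (4.29 ± 0.32, adjusted p = 9.08e-09) and the ubiquitin ligase adaptor Spsb1 7.04-fold (2.82 ± 0.23, adjusted p = 2.82e-08). Testin, a Sertoli cell protein of the junctions with germ cells, rose 18.4-fold (4.20 ± 0.53, adjusted p = 6.96e-06), and the neuropeptide Calcb 17.7-fold (4.15 ± 0.52, adjusted p = 7.67e-06). S100a9 and S100a8, calcium-binding proteins abundant in neutrophils and monocytes, rose 27.3-fold and 18.0-fold (4.77 ± 0.75 and 4.17 ± 0.62, adjusted p = 0.000115 and 6e-05). Their corn oil signals, 19.7 ± 7.99 and 3.19 ± 0.853, lay below the 40th percentile of the arrays, so that these folds also depend on the added 16. The signals of S100a9 after MEHP were 5972, 258.3 and 518.9 in animals 57, 58 and 59, and those of Reg3b, a secreted lectin that rose by 4.22 ± 0.83, were 4413, 116.1 and 299.3. Without animal 57 the change of Reg3b was 2.74. Animal 57 also had the lowest Leydig cell score of all arrays, 8.18, and the highest residual SD, 0.421. The residual SD of animal 58 was almost the same, 0.42, so that animal 57 was not the only array far from its group mean. The log2 ratios of 3' to 5' signals of animal 57 were the lowest of all arrays for actin (0.659) and hexokinase (0.231). Without animal 57 the count of 1852 at 12 h was 1015 (623 higher, 392 lower), and without corn oil animal 62 it was 1203 (803 higher, 400 lower).

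Enzymes of androgen synthesis fell at 12 h. Cyp17a1 fell to 0.0964 of its corn oil level (-3.37 ± 0.55, adjusted p = 0.000154). Its mean signals were 5934 ± 1301 and 1010 ± 1177, with 112.5, 2343 and 575 in MEHP animals 57, 58 and 59. The 0.0964 comes from means of log2 values, and the fall of the mean signals was smaller. The low signal of animal 57 weighs more in the former. Cyp11a1, which cleaves the side chain of cholesterol, and Hsd3b1, which acts after it, fell to 0.292 and 0.401 (-1.78 ± 0.36 and -1.32 ± 0.18, adjusted p = 0.00174 and 2.39e-05). Lhcgr, the receptor for luteinizing hormone, fell to 0.462 (-1.11 ± 0.24, adjusted p = 0.00342, and -0.67 without MEHP animal 57), and Nr5a1, a transcription factor that activates steroidogenic genes, by 0.70 ± 0.17 (adjusted p = 0.00966). The HDL receptor Scarb1 fell by 1.03 ± 0.28 (adjusted p = 0.0203), a call lost without corn oil animals 60 (adjusted p = 0.0784) or 62 (adjusted p = 0.0862) or MEHP animal 59 (adjusted p = 0.0916). Hsd11b1, which regenerates active glucocorticoid, rose 2.93-fold (1.55 ± 0.22, adjusted p = 3.48e-05). Star rose as well, 2.61-fold (1.38 ± 0.38, adjusted p = 0.0218), but its other probe set did not pass (0.49, adjusted p = 0.518). The Star call at 12 h was lost without corn oil animals 60 (adjusted p = 0.0992) or 61 (adjusted p = 0.116) or MEHP animal 58 (adjusted p = 0.0731).

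Of 15 steroidogenesis genes 6 fell, 2 rose and 7 did not pass at 12 h (8 and 3 adjusted over the list alone), with a median of -1.02 (adjusted p = 0.0491, and adjusted p = 0.464 with an estimated correlation). Of 11 Leydig cell markers 5 fell, 2 rose and 4 did not pass (7 and 2), with a median of -1.27 (adjusted p = 0.0491, and adjusted p = 0.404 with an estimated correlation). The peptide hormone Insl3 was lower by 1.32 on average without passing (-1.32 ± 0.48, adjusted p = 0.0947). The steroidogenesis call was lost without MEHP animal 59 (adjusted p = 0.15) or corn oil animal 62 (adjusted p = 0.117). It was also lost, with adjusted p from 0.0501, without corn oil animals 40, 41, 48, 36 and 7 and MEHP animals 43, 44, 45, 49, 50 and 32. The Leydig marker call was lost without corn oil animal 62 (adjusted p = 0.195) or MEHP animal 59 (adjusted p = 0.112). It was also lost, with adjusted p from 0.0511, without corn oil animals 40, 41, 47, 48, 53, 34, 35, 36 and 7 and MEHP animals 43, 44, 45, 49, 50, 51 and 32. Other genes with large decreases were Svs5, a seminal vesicle secretory protein (-3.04 ± 0.45, adjusted p = 5.66e-05), and Cmtm8, a regulator of EGF receptor turnover (-2.36 ± 0.28, adjusted p = 3.1e-06). The lipase inhibitor G0s2 (-2.16 ± 0.32, adjusted p = 5.25e-05) and Igfbp5, which binds insulin-like growth factors (-1.82 ± 0.25, adjusted p = 1.84e-05), fell as well. Of the 3 other probe sets of Igfbp5 1 did not pass (-0.97, adjusted p = 0.0681).

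Some genes of the extracellular matrix and the tubule wall rose at 12 h. Plaur, the urokinase receptor, rose 11.1-fold (3.48 ± 0.38, adjusted p = 9.76e-07), Timp1, an inhibitor of metalloproteinases, 6.47-fold (2.69 ± 0.33, adjusted p = 4.14e-06) and the protease inhibitor A2m 2.98-fold (1.57 ± 0.17, adjusted p = 6.49e-07). Of 22 matrix genes 9 rose and 0 fell by limma (13 and 1 adjusted over the list alone), with a median of 0.61 (adjusted p = 1.12e-06, and adjusted p = 0.131 with an estimated correlation). Of 12 peritubular myoid markers 7 rose and 0 fell by limma (8 and 0), with a median of 0.81 (adjusted p = 9.24e-07, and adjusted p = 0.154 with an estimated correlation). Tagln and Acta2, smooth muscle proteins, rose 2.82-fold and 2.45-fold (1.5 ± 0.17 and 1.29 ± 0.17).

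Of 26 junction genes 6 rose, 2 fell and 18 did not pass at 12 h (10 and 3 adjusted over the list alone). The integrin subunits Itga6 and Itgb1 and N-cadherin, Cdh2, rose 3.63-fold, 2.24-fold and 2.98-fold (1.86 ± 0.29, 1.16 ± 0.20 and 1.58 ± 0.25), whereas the claudin Cldn5 fell by 0.78 ± 0.15 and the gap junction protein Gja1 by 0.74 ± 0.13. The other probe set of Gja1 gave -0.50 (adjusted p = 0.176). The median of the junction list was 0.15 (adjusted p = 0.0354, and adjusted p = 0.677 with an estimated correlation), a call lost without corn oil animal 61 (adjusted p = 0.0875) or MEHP animals 57 (adjusted p = 0.113) or 59 (adjusted p = 0.108). Of 16 Sertoli cell markers, Ctsl, a secreted cathepsin, rose 2.56-fold (1.36 ± 0.23, adjusted p = 0.00021) and the inhibin subunit Inhbb fell by 1.32 ± 0.36 (adjusted p = 0.0197), with 1 and 1 adjusted over the list alone. The Inhbb call was lost without corn oil animals 60 (adjusted p = 0.0814) or 62 (adjusted p = 0.0754) or MEHP animal 57 (-0.56, adjusted p = 0.159). The Sertoli list did not move as a group (median 0.01, mean -0.00157, test direction up, adjusted p = 0.792), and Vim and Inha, a filament protein and an inhibin subunit of Sertoli cells, did not pass (0.31 ± 0.11 and -0.34 ± 0.15, adjusted p = 0.087 and 0.198).

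Macrophage and monocyte markers were higher in 17 of 19 members at 12 h, and 4 rose (8 adjusted over the list alone), with a median of 0.38 (adjusted p = 2.72e-05, and adjusted p = 0.313 with an estimated correlation). Without MEHP animal 57 their mean of 0.552 became 0.284 (adjusted p = 0.00483). The endotoxin coreceptor Cd14 rose 3.06-fold (1.62 ± 0.27, adjusted p = 0.000182) and the mannose receptor Mrc1 1.90-fold (0.92 ± 0.12, adjusted p = 1.32e-05). Lysozyme, Lyz2, rose by 2.11 ± 0.41, with signals of 7260, 1027 and 965.3 in animals 57, 58 and 59, and by 1.16 without animal 57. The death receptor Fas rose 5.27-fold (2.40 ± 0.32, adjusted p = 1.68e-05), the TNF receptor Tnfrsf1a 4.25-fold (2.09 ± 0.23, adjusted p = 1.39e-06) and the cell cycle inhibitor Cdkn1a 3.08-fold (1.62 ± 0.17, adjusted p = 5.92e-07). Of 17 genes of apoptosis and p53, 5 rose and 1 fell (7 and 1), with a median of 0.36 (adjusted p = 0.000851, and adjusted p = 0.124 with an estimated correlation). The proapoptotic Bcl2l11 was among those that rose (0.65 ± 0.17, adjusted p = 0.0164), but its other probe set gave -0.20, and its call was lost without corn oil animal 61 (adjusted p = 0.0796) or MEHP animal 57 (0.34, adjusted p = 0.182).

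Genes of the PPAR list, many of them of fatty acid oxidation, changed in both directions at 12 h. Of 25 genes 5 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.0264, and adjusted p = 0.464 with an estimated correlation), a call lost without MEHP animal 57 (mean -0.0521 beside -0.177, adjusted p = 0.153). Without MEHP animal 58 the mean was -0.282, and with no filter it was -0.0362 (adjusted p = 0.116). The thioesterase Acot1 fell by 1.07 ± 0.16 (adjusted p = 4.47e-05), the fatty acid carrier Fabp3 by 1.00 ± 0.19 (adjusted p = 0.000866, and 0.62 without animal 57) and Cpt1a, which admits fatty acids to the mitochondrion, by 0.60 ± 0.10 (adjusted p = 0.000131). The other probe set of Cpt1a gave -0.36 (adjusted p = 0.138). Angptl4, an inhibitor of lipoprotein lipase, rose 2.94-fold (1.56 ± 0.26, adjusted p = 0.000205). The lipid droplet protein Plin2 also rose (0.83 ± 0.20), but its other probe set gave -0.01, and its call was lost without MEHP animal 57 (0.46, adjusted p = 0.0863). Among 20 cholesterol genes, Dhcr7, the enzyme of the last step of synthesis, fell to 0.381 (-1.39 ± 0.14, adjusted p = 2.23e-07), and the list did not move as a group (median -0.08, 1 fell over all genes and over the list alone, adjusted p = 0.464). Insig1, a sterol-regulated inhibitor of SREBP, did not pass at any time, with changes from -0.07 to 0.07.

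Other signalling genes changed in both directions at 12 h. Of 13 glucocorticoid responsive genes 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.39 (adjusted p = 0.0166, and adjusted p = 0.386 with an estimated correlation), a call lost without MEHP animal 57 (adjusted p = 0.142). Dusp1 rose 6.85-fold (2.78 ± 0.26) and the sulfotransferase Sult1a1 fell by 1.37 ± 0.19 (adjusted p = 2.45e-05). The transcription factor Klf9 rose by 0.63 ± 0.13, but its other probe set gave -0.05. Of 21 genes of TGF-beta, activin and inhibin signalling, 4 rose, Fst, Inhba, Tgfb3 and Id3, and Inhbb fell (4 and 1 adjusted over the list alone), while the list did not move as a group (median 0.01, adjusted p = 0.273). The activin subunit Inhba rose by 1.62 ± 0.37, a call lost without MEHP animal 57 (adjusted p = 0.0713), as were those of Tgfb3 (0.56, adjusted p = 0.186) and Id3 (adjusted p = 0.0638). The Tgfb3 call was also lost without corn oil animal 61 (adjusted p = 0.062).

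The effect of MEHP differed between times for 608 probe sets (3460 at an unadjusted p under 0.05). Fst, Gbp4 and Cxcl1 had the smallest interaction p values of the named genes (adjusted p = 5.29e-05 each), followed by Spsb1 (adjusted p = 6.19e-05), Ccn2, Ccn1 and Cebpd (adjusted p = 6.68e-05 each). The change of Fst was -0.28, 0.07, 0.11, 0.34 and 4.24 at 1, 2, 3, 6 and 12 h (standard error 0.35), whereas that of Ccn2 was 2.01 at 3 h (standard error 0.24). Star had a change of -1.82 at 6 h and 1.38 at 12 h (interaction adjusted p = 0.00379). Those of Egr1, Fos, Nr4a1, Scarb1 and Insl3 did not pass (adjusted p = 0.306, 0.148, 0.163, 0.102 and 0.401), so that a difference between times was not shown for them. The count of 608 was 298, 346, 349 and 1213 without corn oil animals 60, 61 and 62 and MEHP animal 58 of 12 h, and with the RNA integrity number as a covariate it was 289.

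Of the 24 list scores, 10 differed between times. The lists were immediate early genes (adjusted p = 0.000432), cytokines (adjusted p = 6.82e-09), steroidogenesis (adjusted p = 0.012), Leydig markers (adjusted p = 0.00612) and apoptosis (adjusted p = 0.00497). The others were glucocorticoid responsive genes (adjusted p = 0.00267), NRF2 (adjusted p = 0.00612), matrix (adjusted p = 0.000441), myoid markers (adjusted p = 0.00497) and macrophage markers (adjusted p = 0.00612). The mean score of the cytokine list differed by -0.00665, 0.29, 0.67, 0.75 and 2.34 at 1, 2, 3, 6 and 12 h (standard error 0.13), and that of the Leydig markers by 0.10, -0.06, 0.45, -0.65 and -0.83 (standard error 0.21). Macrophage markers went from -0.44 at 2 h to 0.55 at 12 h (standard error 0.14), and the corn oil and MEHP arrays of 2 h differed in spike level. Leydig marker scores of corn oil animals differed too, with 8.861 to 8.941 at 3 h and 9.555 to 9.648 at 6 h.

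**Figure D4:**
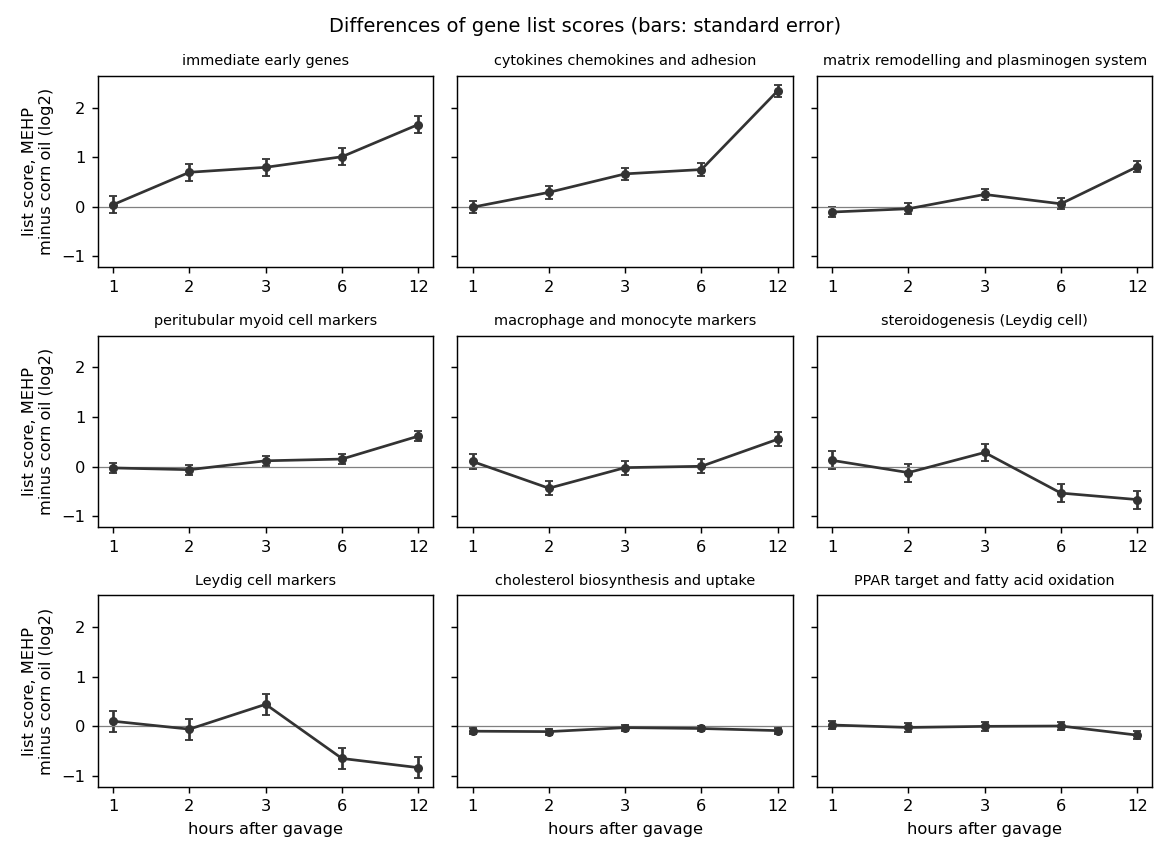
Difference in gene list score, MEHP minus corn oil, with standard errors from the fit of 30 arrays. Times are equally spaced on the axis.

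Probe sets that rose at 3 h or 6 h mostly rose at 12 h as well, whereas most of those called at 2 h were not called at 12 h. All 9 probe sets that rose at 3 h and 33 of the 38 that rose at 6 h also rose at 12 h, where 0.455 and 1.92 would be expected of independent calls, and 7 of the 9 of 3 h rose at 6 h (0.0161 expected). Of the 47 that rose at 2 h, 10 rose at 12 h (2.38 expected), and of the 93 that fell at 2 h, 5 fell at 12 h (3.42 expected) and 1 rose. Of the 5 that fell at 6 h, 2 fell at 12 h, Nat8f5 among them, and Star rose. The overlap of 33 was 21, 16, 14 and 12 without corn oil animals 34, 35 and 36 and MEHP animal 32 of 6 h, and 58 without MEHP 3 h animal 49.

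Over the 5 times together, MEHP changed 999 probe sets at any time (3706 at an unadjusted p under 0.05) and 509 on average over the times, 349 higher and 160 lower. The mean list score over the times differed for immediate early genes (0.84, permutation p = 1e-05, the smallest the 100000 permutations can give, adjusted p = 0.00024), and cytokines (0.81, adjusted p = 0.00048). It also differed for glucocorticoid responsive genes (0.17, adjusted p = 0.0265), apoptosis genes (0.14, adjusted p = 0.0265) and cholesterol genes (-0.07, adjusted p = 0.0265). The permutations compare a list's own score, whereas camera compares its members with the other genes. Camera called the cholesterol list at no time (adjusted p from 0.0541 to 0.557). The count of 999 was 649 and 651 without corn oil 12 h animals 60 and 62 and 1564 without MEHP 12 h animal 58, and the count of 509 was 938 without MEHP 12 h animal 58. Among corn oil animals 7 probe sets differed between times, and 4390 had an unadjusted p under 0.05, against 1060 expected by chance. Mean spike levels of corn oil arrays differed too, with 11.04 and 11.09 at 1 h and 6 h, and 11.72 and 11.69 at 3 h and 12 h. With the spike level as a covariate the count was 0. Time and array processing can therefore not be told apart here. Every single omission apart from corn oil 3 h animal 53 and MEHP 12 h animal 58 moved the count of 7. It fell to between 0 and 3 for most, and rose to 49, 92, 147 and 1936 without corn oil 3 h animal 54, MEHP 3 h animal 49, MEHP 12 h animal 57 and corn oil 2 h animal 7.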

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

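The tests of the processing of the 2 h corn oil arrays and of the share of Leydig cells were chosen after the result was seen.

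The effect of MEHP differed between times for 608 probe sets, and 19 of 57 control probe sets differed between the groups at 2 h. The list scores whose effect differed between times were cytokines (adjusted p = 6.82e-09), immediate early genes (adjusted p = 0.000432), matrix remodelling (adjusted p = 0.000441), and glucocorticoid responsive genes (adjusted p = 0.00267). The others were apoptosis and myoid markers (adjusted p = 0.00497 each), NRF2, Leydig and macrophage markers (adjusted p = 0.00612 each) and steroidogenesis (adjusted p = 0.012). Among single genes the adjusted p was 5.29e-05 for Cxcl1, Fst and Gbp4, 6.19e-05 for Spsb1, 6.68e-05 for Cebpd and Ccn2, 0.00111 for Ccl2, 0.00379 for Star, 0.012 for Fas and 0.0217 for Cyp17a1. A formal test for outlying animals within groups of 3 was not run. Single arrays were assessed by array weights and by leaving out each animal in turn. The lowest weights were 0.154 (MEHP 12 h animal 57), 0.182 (MEHP 3 h animal 49) and 0.227 (corn oil 2 h animal 48). The highest was 4.79 (corn oil 2 h animal 47).

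Whether the processing of the 2 h corn oil arrays caused part of the calls at 2 h could not be decided. The gap between those arrays and the other corn oil arrays met a median of 70.4% of each fall over the 93 probe sets and of 58.1% of each rise over the 47. Selection by p alone can give such shares: at 1 h, where 0 were called, the 93 and 47 of smallest p gave 54.5% (quartiles 36.6 and 75.8) and 62.6% (38.6 and 75.9), but the 93 gave 41% at 3 h (26.9 and 54), where 0 fell, 25.2% at 6 h and -0.777% at 12 h, and the 47 gave 26.7%, 20.9% and 4.95%. A corn oil 2 h animal 7 that had received MEHP was argued against, since on a scale from the other 2 h controls (0) to the 2 h MEHP animals (1) it lay at -0.166 for the probe sets that rose at 6 h, against 0.947 to 1.11 in the MEHP animals. Dates of handling or scanning are not given in the sources used here, so that a separate day for these arrays stays open.

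The decrease of Leydig cell genes at 12 h could reflect fewer Leydig cells in the tissue taken, which stays open. Of the Leydig markers 2 rose, Star and Hsd11b1, while 5 fell, but Star's other probe set did not pass (0.49, adjusted p = 0.518) and its call was lost without animals 60, 61 or 58, so that Hsd11b1 alone remains. With the spermatid score as a covariate the median of the 5 markers that fell was -1.29, beside -1.31 without it, and all 5 were still called. The score itself differed by only 0.0471 (standard error 0.321) between the 12 h groups, so the covariate could change little. This does not decide whether an axis shared with spermatid genes played a part. A change of transcription in Leydig cells remains a hypothesis, and so does cell loss together with a rise of Hsd11b1 in other cells.

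S100a8 and S100a9 at 12 h were highest in animal 57, but a single animal was argued against as the cause, since the highest adjusted p of either gene without any 1 animal was 0.00115. Neutrophils in the tissue may be a source but could not be tested: besides S100a8 and S100a9 the list had 1 tested member, Selp (0.421), which is better known from platelets and endothelium. Members under the filter were not tested, and differed by 1.49 (Mmp8), 1.32 (Csf3r), 0.612 (Cxcr2), 0.383 (Np4), 0.128 (Camp), -0.13 (Defa5) and -0.092 (a second probe set of Selp).

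Other splits of the animals were compared with the real one. The 6 animals of a time allow 10 splits, too few for a share under 0.05. The real split gave 0 probe sets at 1 h, 140 at 2 h, 9 at 3 h, 43 at 6 h and 1852 at 12 h, and the highest other split gave 0, 3, 0, 0 and 2. As many as the real count were given by 10 of 10 splits at 1 h and by 1 of 10, the real one, at each other time. For results over all times 100 splits within times were drawn, the real one included, and for the times of corn oil animals 100 that exchanged these 15 animals between times. For each, the share of splits that reached the real count lay under 0.05, the limit set beforehand for counting against chance. Such a share does not exclude chance outright. For any time 1 of 100 reached the real 999 (highest other 766), and for time dependence 2 of 100 reached 608, where another split gave 628. A draw within times can keep the real 12 h groups or swap them whole, and no other 12 h split gave more than 2. High counts of other splits may therefore hold the real 12 h effect and are not read as counts by chance. These splits also remove any effect shared by the times, so they do not test time dependence by itself. For the average over times 1 of 100 reached 509 (highest other 83), for the list shifts 1 of 100 reached 39 (28), and for the lists that differ between times 1 of 100 reached 10 (8). For the sentinel genes 1 of 100 reached 21 (10), for the overlap of 6 h and 12 h 1 of 100 reached 33 (0), and for the times of corn oil animals 1 of 100 reached 7 (1). Corn oil arrays of different times differed in spike level as well, so the last does not tell time from array processing.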

How the results depend on the processing

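Array weights, the covariates for array median, spermatid score and spike level, the omission of arrays of deviating median or of the 2 h arrays, and the 1 h corn oil animals as controls for 2 h were chosen after the result was seen. Counts not named below moved by less than 1.5 times. The cause of a moved count was not tested, except that by construction a 1.5-fold minimum can only lower a count.

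At 1 h (0) the count was 2 when adjusted over the 5 times. At 2 h (140) it was 211 with quantile normalization, 49 with no filter, 237 with the 60th percentile filter, 63 with no trend and 60 with RNA integrity. It was 3281 with array weights, 664 with the array median, 1214 with the spermatid score, 34 without arrays of deviating median, and 13 with the spike level. It was 4 against 1 h corn oil animals, 1 from the 6 arrays alone, 83 at 1.5-fold or more and 222 adjusted over the 5 times. At 3 h (9) it was 1109 with array weights, 3 without arrays of deviating median, 1 from the 6 arrays alone and 44 adjusted over the 5 times. At 6 h (43) it was 20 with RNA integrity, 489 with array weights, 75 with the array median, 4 without arrays of deviating median, 10 from the 6 arrays alone and 85 adjusted over the 5 times. At 12 h (1852) it was 2846 with the spermatid score, 2961 without arrays of deviating median, 254 from the 6 arrays alone (223 higher, 31 lower) and 1134 adjusted over the 5 times.

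For any time (999) the count was 5459 with array weights, 1602 with the array median and 2018 with the spermatid score. For time dependence (608) it was 289, 5613, 1067 and 1553 with RNA integrity, array weights, array median and spermatid score, and 359 without the 2 h arrays. For the average (509) it was 979 with gavage volume, 1741, 814 and 860 with weights, array median and spermatid score, and 312 with the spike level. For corn oil times (7) it was 4 with median centring, 18 with log2(signal + 64), 3 with no filter, 12 with the 60th percentile, 2 with no trend and 0 with RNA integrity. It was 872 with gavage volume, 10780 with array weights, 74 with the array median, 326 with the spermatid score, 1 without arrays of deviating median, 0 with the spike level and 0 without the 2 h arrays. List shifts (39) were 8 with an estimated correlation, lists that differ between times (10) were 17 with the spermatid score, and sentinel calls (21) were 33 with array weights. The overlap of 6 h and 12 h (33) was 18 with RNA integrity, 191 with weights, 57 with the array median and 4 without arrays of deviating median.

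With 1 animal left out the counts ran from 0 to 1 at 1 h, 11 to 330 at 2 h, 5 to 37 at 3 h, 13 to 75 at 6 h, and 1015 to 2686 at 12 h. They ran from 649 to 1564 for any time, 298 to 1213 for time dependence, 367 to 938 for the average and 0 to 1936 for corn oil times. They ran from 33 to 42 for list shifts, 10 to 14 for lists that differ between times, 18 to 23 for sentinel calls and 12 to 58 for the overlap. Of the calls themselves, 123 of 140 at 2 h stood with quantile normalization, 59 with RNA integrity and 7 with the spike level, and 1745, 1445 and 1820 of 1852 at 12 h.

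Directions reversed with gavage volume for the junction list at 1 h (0.0313) and the spermatid list at 1 h (-0.071), with array weights for Ccl2 at 2 h (1.35), and in the other probe sets of Plin2 (-0.013), Bcl2l11 (-0.20) and Klf9 (-0.048) at 12 h. With the spike level the mean of the spermatogonia list at 2 h changed sign (0.0615) but its test direction did not, so that this counts as lost below. For the 165 named gene calls 2357 of 2663 alternatives gave the call in the same direction, 303 lost it and 3 reversed it, and 4528 of 4950 single omissions gave it. For the 39 list calls these were 498 of 583, with 83 lost and 2 reversed, and 1075 of 1170. Robust moderation and no trend were not run for lists, as camera uses neither, nor was the spermatid list under its own score. Omission of 8 arrays left 1 corn oil array at 3 h and at 6 h.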

Other observations

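The tests of whether probe sets called at 1 time leaned the same way at another were chosen before their result was seen, on sets found in these data.

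Transcription factors of the circadian output moved apart at 12 h, where the folds of Nfil3 and Bhlhe40 depend on the added 16, as their corn oil signals lay below the 40th percentile of the arrays. Nfil3, a repressor that opposes Dbp, rose 8.83-fold (3.14 ± 0.29, adjusted p = 1.12e-07), and the repressor Bhlhe40 5.30-fold (2.41 ± 0.34, adjusted p = 2.61e-05). Dbp itself and the activator Npas2 fell (-1.01 ± 0.17 and -1.02 ± 0.19, adjusted p = 0.000184 and 0.000804), as did Per2 and Per3. The calls of Per2 and Per3 were lost without corn oil animals 60 (adjusted p = 0.0769 and 0.0835), 61 (adjusted p = 0.14 and 0.0575) or 62 (adjusted p = 0.0768 and 0.0529) or MEHP animal 57 (adjusted p = 0.361 and 0.0757). Without animal 57 the change of Per2 was -0.26 beside -0.62, and the other probe set of Per3 gave -0.37 (adjusted p = 0.655). Of 16 clock genes 2 rose and 4 fell (3 and 5 adjusted over the list alone), and the list did not move as a group (median -0.16, mean 0.11, test direction down, adjusted p = 0.681).

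Several antioxidant and chaperone genes rose at 12 h, where the folds of Gpx2 and Srxn1 depend on the added 16. Gpx2, a glutathione peroxidase, rose 6.56-fold (2.72 ± 0.48, adjusted p = 0.000377), Srxn1, which repairs peroxiredoxins, 3.97-fold (1.99 ± 0.38, adjusted p = 0.000805) and the mitochondrial superoxide dismutase Sod2 2.09-fold (1.07 ± 0.21, adjusted p = 0.000972). Without MEHP animal 57 the changes of Gpx2 and Sod2 were 1.78 and 0.61. Of 17 NRF2 genes 5 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0143, and adjusted p = 0.319 with an estimated correlation). Of 13 heat shock genes 5 rose and 0 fell by limma (6 and 0), with a median of 0.35 (adjusted p = 0.00171, and adjusted p = 0.392 with an estimated correlation), a call lost without MEHP animal 57 (mean 0.22 beside 0.464, adjusted p = 0.113). The cochaperone Bag3 rose 2.81-fold (1.49 ± 0.22) and Hspb1 1.78-fold (0.84 ± 0.17). Of 19 genes of endoplasmic reticulum and amino acid stress 3 rose and 3 fell (3 and 3), with no group shift (median 0.04, adjusted p = 0.568). Ppp1r15a rose by 1.40 ± 0.19 and Xbp1 by 0.70 ± 0.14, whereas Phgdh and Asns, enzymes of serine and asparagine synthesis, fell by 1.30 ± 0.26 and 0.77 ± 0.16 (Phgdh by 0.72 without animal 57). Among 11 endothelial markers the VEGF receptor Kdr rose by 1.03 ± 0.22 and Cldn5 fell by 0.78 ± 0.15 (1 and 1, list adjusted p = 0.562).

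Germ cell and blood cell lists had 0 members past the threshold at 12 h by limma and no group shift. The medians were -0.23 for 7 spermatogonia markers (adjusted p = 0.1), -0.08 for 13 spermatocyte markers (adjusted p = 0.331), 0.04 for 14 spermatid markers (adjusted p = 0.801), 0.03 for 7 lymphocyte markers (adjusted p = 0.562) and 0.11 for 5 erythrocyte markers (adjusted p = 0.865). Of the neutrophil list 3 of 14 genes were measured and of the epididymis and rete list 2 of 12, too few for a test. Median, mean and test direction also differed in sign, without a call, for immediate early and PPAR genes at 1 h, for clock, endothelial and spermatid genes at 2 h and for PPAR, TGF-beta, endothelial and macrophage genes at 3 h. At 6 h this held for the PPAR, endoplasmic reticulum, heat shock, matrix, spermatogonia, macrophage and erythrocyte lists.

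The probe sets that rose at 6 h were also higher at 2 h (34 of 38, median 0.54) and at 3 h (37 of 38, median 0.86), with adjusted p = 0.0245 and 0.00105 with an estimated correlation over 24 combinations. At 1 h 22 of 38 were higher (median 0.05), so that a lean at 1 h was not shown (p = 0.0549, and p = 0.509 with an estimated correlation). Of the probe sets that fell at 12 h 575 of 780 were lower at 1 h (median -0.08), 554 at 2 h (median -0.13), 405 at 3 h (median -0.01) and 483 at 6 h (median -0.05), so that the lean did not grow with time. The test at 6 h gave p = 0.00016 with the preset correlation and p = 0.428 with an estimated one, so that a lean stays open. At 1 h and 2 h these were 0.00102 and 3.86e-05, and 0.49 and 0.388. Of the probe sets that rose at 12 h 818 of 1072 were higher at 3 h and 872 at 6 h (adjusted p = 0.522 and 0.165 with an estimated correlation). At 1 h and 2 h, 678 and 642 of these 1072 were lower (medians -0.0546 and -0.0726). A lean down at 1 h and 2 h was thus not particular to the probe sets that fell at 12 h. A p of 0.05 or more with an estimated correlation had been set beforehand as evidence against a lean, but such a p does not show that there was none.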
